A study of Mus musculus with 17 samples.

How the data were processed

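RNA from the abdominal aorta of 17 male mice was measured on Affymetrix Mouse Transcriptome Assay 1.0 arrays, 1 array per mouse. Per the labels, 100 ng of total RNA was turned into biotin-labelled cDNA before hybridization. The labels name Trizol for the RNA extraction and the series' design text names a column kit, so the extraction is not settled here. The authors processed the arrays with RMA in Partek at the level of transcripts, and the deposited values are in log2 units, the log base being read from the values themselves. The versions of these tools and the build of their annotation are not given in the sources used here. The authors describe a filter of a signal of at least 4.2 on at least 3 arrays, a two-way fit with an interaction and a false discovery rate, and the exclusion of an RNA of poor quality. The deposited table still held all 72688 probe sets, so the filter had not been applied to it.

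Of these probe sets, 6732 were controls and 65956 measured transcripts, of which 30638 carried 1 gene symbol, 2176 several and 33142 none. Symbols were matched to the mouse RefSeq gene table for 30636 probe sets, and 330 were updated from a synonym. The authors' stated filter was then applied, which left 22353 probe sets and, for the 279 genes with several, 1 probe set per gene. This gave 22039 genes tested, of which 20978 were autosomal, 1045 X-linked and 7 Y-linked by the RefSeq annotation. Of the called genes with several probe sets for surgery, 1 of 2 had a probe set of the opposite sign. Ddx3y, Ar and Ldlr were not among the genes tested. The 17 value columns were all used.

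Groups were taken from the labels as XY sham (n = 5), XY ORC (n = 4), XX sham (n = 4) and XX ORC (n = 4). A linear model with a mean for each of the 4 groups was fitted in limma 3.58.1 under R 4.3.3, with moderated variances (13 residual and 2.63 prior degrees of freedom). It gave the main effects of genotype and surgery, their interaction, and the effect of each factor within each level of the other, 7 comparisons in all. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Genotype differences are XX minus XY and surgery differences ORC minus sham, on the log2 scale. The arrays' number limits the precision of each value.

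For each comparison 33 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They cover sex-linked genes (Y-linked, escape, distal X segment, its neighbours and other X-linked genes), the vessel wall (smooth muscle, elastic fibre and collagen, matrix proteases, renin-angiotensin, TGF-beta), hormones (sex steroid, androgen response), immune and inflammatory genes (macrophage, inflammatory, interferon, lymphocyte), other cell types (endothelial, fibroblast, white and brown adipocyte, skeletal muscle, nerve, sympathetic neuron, adrenal cortex, mesothelial, erythroid), and cell states (cell cycle, immediate early, clock, sterol, oxidative phosphorylation, heat shock, oxidative stress). Camera with an estimated correlation and limma's fry were run beside it. Kidney and liver lists were added after the values had been seen and were not tested as sets. All other lists, the tests, the rule for named genes and most alternatives were set before the data were examined.

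The named genes are, for each term of the two-way design, up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold, completed to 10 by the smallest p-values where fewer pass. For each effect within 1 level they are up to 5 each way, and for each list up to 4 members with the smallest p-values. A fixed set of sex chromosome, receptor and smooth muscle genes is named throughout.

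Alternatives were no filter, a stricter filter (a signal of 6 on 4 arrays), arrays centred on their medians, quantile normalization repeated, every probe set on its own, the probe sets of a gene averaged, a trend with robust moderation, the methods' unmoderated two-way fit, array weights, the RNA integrity number as a covariate, a block for the replicate number, a fit of only the groups compared, and each array left out in turn. Added after seeing the data were the omission of XY sham 1 and XY sham 4 and the means of the sympathetic neuron list, alone or with the brown adipocyte list, as covariates. Other splits of the arrays were fitted, at most 100 per comparison.

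The fit was tested on simulated data with 200 of 22039 genes changed, the genes being independent and the spread of each being equal in all groups. For genotype it recovered 94% of changes of a log2 of 0.5 and 98% of changes of 1, for surgery 90% and 100%, for the interaction 50% and 92%, and for ORC in XX mice 72% and 96%. False calls made up 6.2%, 4.4%, 6.1% and 8% of the calls. The groups of the real data differ in spread (Th had an SD of 1.95 in XY sham and of 0.60 in XX sham mice), so these rates need not hold for them. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.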

Results

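Gene expression was measured in the abdominal aorta of male mice that lack the low density lipoprotein receptor (Ldlr), a background in which a fat-rich diet raises blood cholesterol. The Y chromosome of this strain has lost Sry, the testis-determining gene, and an Sry transgene sits on an autosome, so that males with XX chromosomes can be set against males with XY chromosomes. Mice had sham surgery or orchiectomy (ORC), the removal of the testes. The 17 arrays, 1 per mouse, comprised XY sham (n = 5), XY ORC (n = 4), XX sham (n = 4) and XX ORC (n = 4) mice. The comparisons ask how aortic expression depends on the sex chromosomes, on the testes, and on the combination of both. The series' design text gives RNA collection after 2 weeks of recovery and 1 week of Western diet, and it also describes a longer experiment with angiotensin II infusion. Whether the mice on the arrays were infused is not settled by the sources used here.

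Each value is a log2 signal of 1 gene on 1 array. The median over the 22039 genes tested lay between 6.45 and 6.54 on every array, and the median of the negative control probe sets lay between 3.53 and 3.87. RNA integrity numbers in the labels ran from 9.4 to 9.8, with a mean of 9.54 ± 0.13 (SD) in XY sham, 9.65 ± 0.10 in XY ORC, 9.70 ± 0.115 in XX sham and 9.68 ± 0.05 in XX ORC mice. Across genes, arrays of 1 group correlated at r of 0.9619 to 0.9953 and arrays of different groups at 0.9502 to 0.9945 (genes are not independent replicates). The number of arrays limits the precision of every comparison.

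The sex chromosome genes matched the labels of all 17 arrays. Xist, the RNA that coats the inactive X chromosome, had a log2 signal of 9.50 to 10.13 in the 8 XX mice and of 4.13 to 4.35 in the 9 XY mice. Uty, a Y-linked histone demethylase gene, lay between 5.92 and 6.40 in XY mice and between 3.88 and 3.99 in XX mice. Eif2s3y and Kdm5d, also on the Y chromosome, separated the complements without overlap, at means of 6.73 and 5.95 in XY sham against 4.50 and 4.13 in XX sham mice. The low values stand near the negative controls, so the folds of these genes are limited by the floor of the array.

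**Figure D1:**
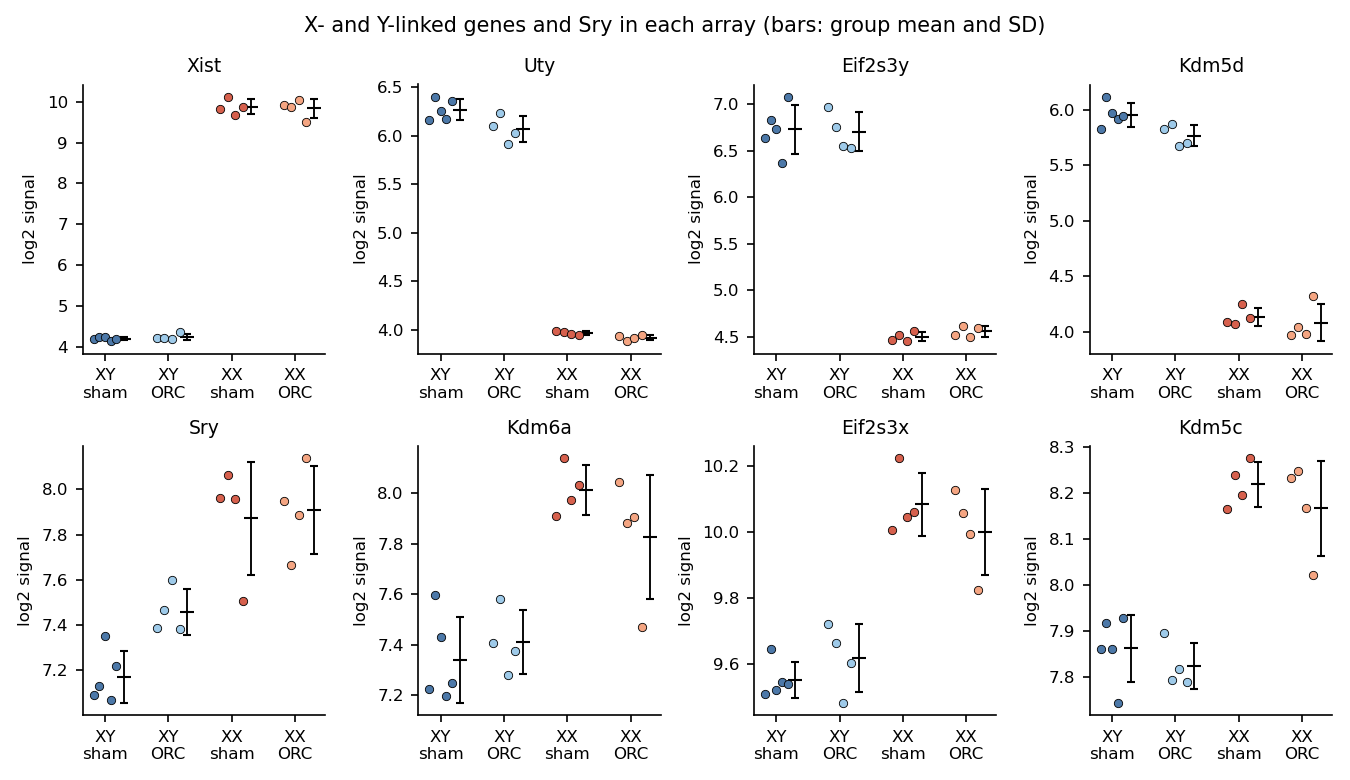
Log2 signal (vertical axis) of X- and Y-linked genes and of Sry, here from the transgene, in each mouse (points) of the XY sham, XY ORC, XX sham and XX ORC groups (horizontal axis), with the group mean and SD as bars. Xist lies between 9.50 and 10.13 in the 8 XX mice and between 4.13 and 4.35 in the 9 XY mice, and Uty, Eif2s3y and Kdm5d show the opposite order.

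Markers of tissues next to the aorta were measured on the arrays, at levels that differed between and within groups. The mean signal of the sympathetic neuron and chromaffin genes, among them Th and Dbh of catecholamine synthesis, was 7.97 ± 1.40 (SD, n = 5) in XY sham, 7.06 ± 0.58 (n = 4) in XY ORC, 6.32 ± 0.31 (n = 4) in XX sham and 8.04 ± 0.39 (n = 4) in XX ORC mice. Within XY sham, mice 1 and 4 reached 9.61 and 9.38 while the other 3 lay between 6.76 and 7.12. Ucp1, the uncoupling protein of brown fat, had a signal of 10.03 to 13.29 on every array, and the brown adipocyte genes averaged 8.22 ± 0.61 in XX sham against 9.12 ± 0.30 in XX ORC mice. Kap, the kidney androgen-regulated protein, reached 10.76, 9.65, 7.84 and 7.29 in XY sham mice 1, 4, 5 and 3 and did not exceed 4.86 in any other array. Klk1, a kidney kallikrein, reached 11.08 in XY sham 1, Cyp11b1 of the adrenal cortex reached 8.70 in XY sham 4, and Alb of the liver exceeded 10 in XY sham 4, XY ORC 1 and XX ORC 1. The first principal component held 45.0% of the variance over all genes, and its 30 highest loadings on the side of Dbh were those of Dbh, Snap25 and 28 snoRNA genes. Many of these snoRNA genes shared 1 identical loading (0.0709), so the component may count 1 signal several times. Kap, Klk1, Cyp11b1 and Alb were chosen after their values were seen.

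**Figure D2:**
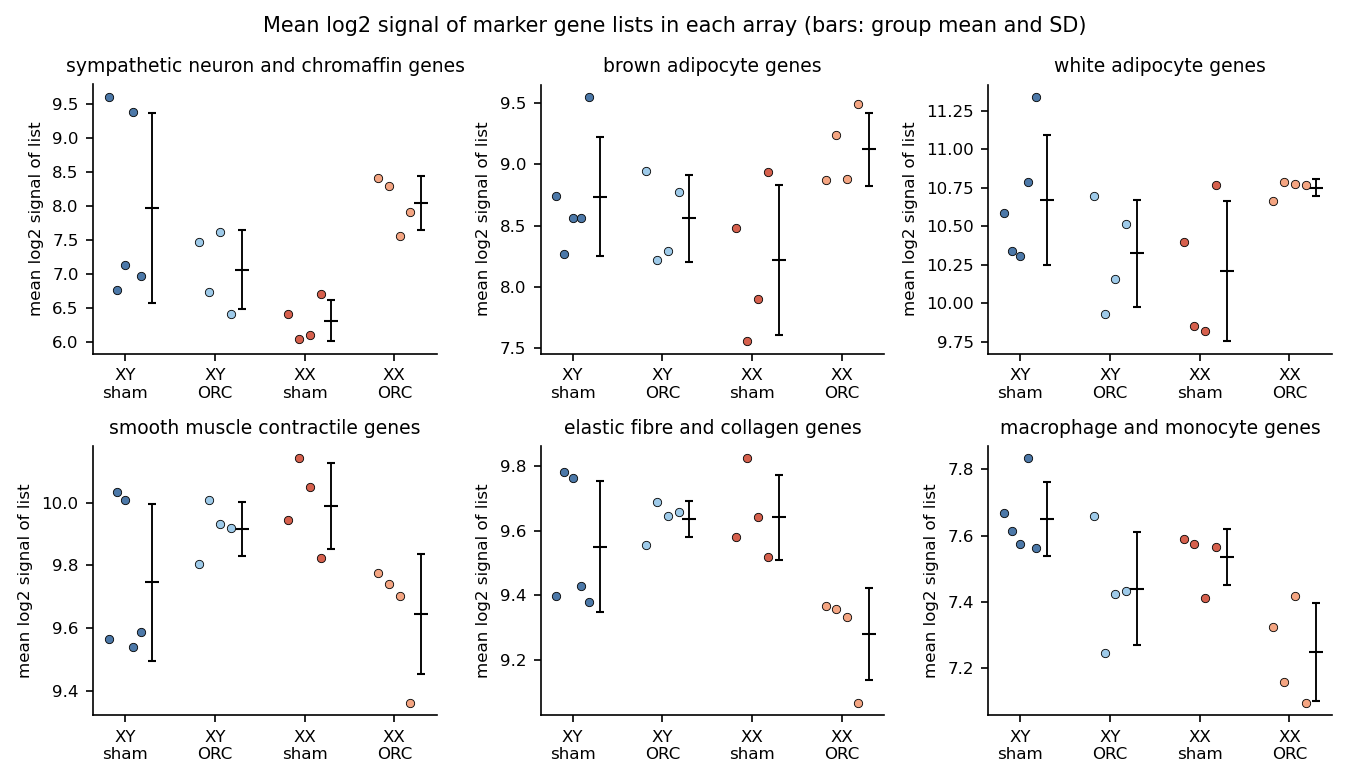
Mean log2 signal over the measured members of 6 marker gene lists (vertical axes) in each mouse (points) by group (horizontal axes), with the group mean and SD as bars. On the sympathetic neuron list XY sham mice 1 and 4 stand at 9.61 and 9.38, and the 4 XX ORC mice, at 7.55 to 8.41, all lie above the 4 XX sham mice, at 6.05 to 6.71.

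For the sex chromosome complement, averaged over surgery, XX mice (n = 8) were compared with XY mice (n = 9). Xist was 50.03-fold higher in XX mice (log2 difference 5.64 ± 0.07, SE), and Uty, Eif2s3y and Kdm5d were lower by log2 differences of -2.23 ± 0.04, -2.18 ± 0.08 and -1.75 ± 0.06. The X-linked genes Kdm6a (0.54 ± 0.08), Eif2s3x (0.46 ± 0.05) and Kdm5c (0.35 ± 0.04), which are partners of Y-linked genes and escape X inactivation, were higher in XX mice. Sry, here from the transgene, was also higher in XX mice, by 0.57 ± 0.08. Outside the sex chromosomes the clock genes Dbp (-0.94 ± 0.14), Nr1d2 (-0.82 ± 0.11), Per2 (-0.60 ± 0.11) and Per3 (-0.46 ± 0.07) were lower in XX mice and Npas2, a transcription factor of the clock, was higher (0.98 ± 0.18). These clock differences lay mainly in sham mice. Dbp stood at 6.98 in XX sham and 8.75 in XY sham, but at 9.05 in XX ORC and 9.16 in XY ORC mice. Among ORC mice limma passed 0 of the 16 clock genes. The fibrillar collagen genes Col1a1 (-0.54 ± 0.09) and Col3a1 (-0.49 ± 0.09) and the inflammatory caspase gene Casp4 (-0.59 ± 0.10) were lower in XX mice. Tsix (0.72 ± 0.07), which overlaps Xist on the opposite strand, and the pseudogenes Pisd-ps3 (0.36 ± 0.07), Dynlt1-ps1 (0.30 ± 0.05) and Pisd-ps1 (0.26 ± 0.05) complete the named genes, and the array may not separate such copies from their parent genes. In all, 32 of 22039 genes passed limma's test at an adjusted p under 0.05, 14 higher and 18 lower in XX mice, and 21 of the 32 were autosomal (6 higher, 15 lower). Ddx3x (0.21 ± 0.06, adjusted p = 0.27), Tlr7 (-0.15 ± 0.09), the angiotensin receptor gene Agtr1a (-0.02 ± 0.16), Acta2 (-0.03 ± 0.07) and Myh11 (-0.02 ± 0.08) did not pass. Ddx3y, Ldlr and the androgen receptor gene Ar were not among the genes tested. The count was 20 with the methods' unmoderated two-way fit, 20 without XY sham mice 1 and 4 (11 higher and 9 lower in both) and 80 with array weights (35 higher, 45 lower). With 1 array left out it ranged from 16 (without XX sham 1 or XX sham 4) to 58 (without XY sham 5).

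All 3 measured genes of the Y-linked list were lower in XX mice (median -2.18, limma camera adjusted p = 3.9e-32, and adjusted p = 3.6e-05 with an estimated correlation). Of 13 X-linked genes known to escape inactivation, 4 were higher, the median was 0.13, and the list's camera adjusted p of 1.3e-10 became an adjusted p = 0.093 with an estimated correlation. Of these, 8 were higher and 1 lower adjusted over the list alone. Of the 1024 other X-linked genes, 2 were higher and the median was 0.01 (camera adjusted p = 0.80). The distal X segment from Tmsb4x to Hccs had a median of -0.05 over 8 genes and its 12 neighbours on the X chromosome a median of -0.02, and neither list passed camera (adjusted p = 0.34 and 0.18). Of 16 circadian clock genes, 1 was higher and 5 were lower, with a median of -0.33 (camera adjusted p = 8.5e-08, and adjusted p = 0.016 with an estimated correlation), and adjusted over the list alone 3 were higher and 10 lower. The clock median was -0.61 in sham mice but -0.08 in ORC mice (camera adjusted p = 2e-07 and 0.14). Of 38 elastic fibre and collagen genes, Col1a1 and Col3a1 were lower, and adjusted over the list alone 14 were, with a median of -0.15 (camera adjusted p = 5.9e-10, but adjusted p = 0.51 with an estimated correlation). The lower list median came from ORC mice, at -0.37 with 36 of 38 members negative. In sham mice it was 0.09 with 27 of 38 members positive (camera adjusted p = 0.25). Of 21 heat shock and unfolded protein genes, Herpud1 was lower (-0.27), and adjusted over the list alone 12 were (median -0.24, camera adjusted p = 9.3e-16, but adjusted p = 0.059 with an estimated correlation). No member of the androgen response list passed limma's test (median -0.08; 9 of 37 at an unadjusted p under 0.05), and the list's camera adjusted p of 1.8e-05 became an adjusted p = 0.084 with an estimated correlation. The macrophage and monocyte list (median -0.14, camera adjusted p = 8.6e-08), the matrix protease list (-0.09, 0.0013), the inflammatory cytokine and adhesion list (-0.04, 0.010) and the cell cycle list (-0.05, 0.039) were lower as groups and the T and B lymphocyte list (0.06, 0.039) was higher. With an estimated correlation these became adjusted p = 0.44, 0.58, 0.51, 0.92 and 0.92. The sympathetic neuron genes differed in the same comparison by a median of -0.36 (camera adjusted p = 0.039, but adjusted p = 0.92 with an estimated correlation), which turned to 0.18 (adjusted p = 0.012) without XY sham mice 1 and 4. Of the 12 lists past camera, the Y-linked and clock lists held with an estimated correlation. Limma's fry passed the Y-linked, escape, clock and heat shock lists (fry adjusted p = 7e-14, 2.05e-07, 0.00044 and 0.0097).

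For the removal of the testes, averaged over the complements, ORC mice (n = 8) were compared with sham mice (n = 9). Sult1e1, the estrogen sulfotransferase, was lower after ORC (log2 -2.49 ± 0.21, SE), at 3.12 to 3.48 in all 8 ORC mice against 4.90 to 6.93 in all 9 sham mice. Its ORC values lie below the medians of the negative controls, so the size of its difference is limited by the floor of the array here and within XY and XX mice. The B cell chemokine Cxcl13 (-1.83 ± 0.24), the complement component C7 (-1.41 ± 0.12), the vasopressin receptor Avpr1a (-1.28 ± 0.10), the dipeptidase Dpep1 (-1.24 ± 0.12), the protease inhibitor Serpina3n (-1.20 ± 0.17), the paraoxonase Pon1 (-1.02 ± 0.16) and the chemokine Ccl8 (-0.92 ± 0.16) were lower as well. Clock genes differed in both directions. Dbp (1.24 ± 0.14), Nr1d2 (0.90 ± 0.11), Per2 (0.83 ± 0.11), Bhlhe41 (0.73 ± 0.10), Hlf (0.72 ± 0.08), Per1 (0.67 ± 0.11), Nr1d1 (0.67 ± 0.14) and Per3 (0.65 ± 0.07) were higher after ORC, and Arntl (-1.34 ± 0.18) and Npas2 (-1.09 ± 0.18) were lower. These clock differences were larger in XX than in XY mice. Npas2 went from 9.14 in XX sham to 7.07 in XX ORC, but from 7.18 to 7.07 in XY mice. Within XY mice limma passed 0 of the 16 clock genes (9 at an unadjusted p under 0.05). Depp1 (0.70 ± 0.15) and Tcap (0.60 ± 0.10), the titin cap gene of striated muscle, were higher. In all, 189 genes passed limma's test, 52 higher and 137 lower after ORC. Xist (0.01 ± 0.07), Uty (-0.13 ± 0.04), Agtr1a (0.09 ± 0.16), Acta2 (-0.07 ± 0.07), Myh11 (-0.04 ± 0.08) and Tlr7 (-0.34 ± 0.09, adjusted p = 0.12) were among those that did not. The count was 89 with the methods' unmoderated two-way fit, 513 without XY sham mice 1 and 4, where 324 were higher and 189 lower, and 303 with array weights (91 higher, 212 lower). With 1 array left out it ranged from 79 (without XX sham 2) to 216 (without XY sham 5).

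Of the 16 clock genes, 9 were higher and 3 lower after ORC (median 0.61, camera adjusted p = 1.9e-07, and adjusted p = 0.041 with an estimated correlation), and adjusted over the list alone 11 were higher and 3 lower. The clock median was 0.84 in XX mice but 0.28 in XY mice. Of 18 fibroblast and adventitial genes, 6 were lower, among them Dpep1, Ly6c1 (-0.32) and Scara5 (-0.39), and 1, Col14a1 (0.35), was higher. That list had a median of -0.26 (camera adjusted p = 6.6e-12, but adjusted p = 0.12 with an estimated correlation), and adjusted over the list alone 12 were lower and 1 higher. Of 24 macrophage and monocyte genes, 5 were lower, among them Mrc1 (-0.51), Itgam (-0.35), Adgre1 (-0.40) and Csf1r (-0.30), with a median of -0.26 (camera adjusted p = 3.7e-16, but adjusted p = 0.12 with an estimated correlation). Of 25 matrix proteases and inhibitors, 5 were lower, among them Adamts5 (-0.58), Plau (-0.38), Timp1 (-0.55) and Mmp9 (-0.28), with a median of -0.17 (camera adjusted p = 2.3e-12, but adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 14 macrophage genes and 12 protease genes were lower. Of 38 elastic fibre and collagen genes, Col4a1 (-0.33), Thbs1 (-0.40) and Col4a2 (-0.28) were among 4 that were lower, and Col14a1 was higher (median -0.14, camera adjusted p = 1.7e-09, but adjusted p = 0.41 with an estimated correlation). Among them 16 were lower and 1 higher adjusted over the list alone. The lower collagen list median came from XX mice, at -0.36 with 36 of 38 members negative. In XY mice it was 0.04 with 23 of 38 members positive (camera adjusted p = 0.64). Of 17 T and B lymphocyte genes, the T cell receptor subunits Cd3e (0.43) and Cd3g (0.54) were higher, and adjusted over the list alone 12 were (median 0.38, camera adjusted p = 3.9e-08, but adjusted p = 0.18 with an estimated correlation). The brown adipocyte genes differed in the same comparison by a median of 0.24 (camera adjusted p = 0.044, but adjusted p = 0.63 with an estimated correlation). Their median was 1.10 in XX mice but -0.12 in XY mice.

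Further lists held 1 gene each past limma's test after ORC. Ace, the angiotensin-converting enzyme gene, was lower (-0.57), 1 of 11 renin-angiotensin genes (median -0.04, camera adjusted p = 0.0063, but adjusted p = 0.18 with an estimated correlation). Hsd11b1 (-0.31), which reactivates glucocorticoids, was lower, 1 of 12 sex steroid and corticoid genes (median -0.01, camera adjusted p = 0.42). The metalloreductase Steap4 (-0.58) was lower, 1 of 37 androgen response genes (median -0.04, camera adjusted p = 0.0037, but adjusted p = 0.21 with an estimated correlation). Gpx3 (-0.54), a secreted glutathione peroxidase, was lower, 1 of 17 oxidative stress genes (median -0.06, camera adjusted p = 0.0063, but adjusted p = 0.18 with an estimated correlation). The platelet gene Pf4 (-0.35) was lower in the erythroid and blood list (median -0.37 over 8 genes, camera adjusted p = 0.00084), Cd34 (-0.42) in the endothelial list (-0.02 over 20 genes, 0.013), and Tcap was higher in the skeletal muscle list (0.10 over 20 genes, 0.0017). With an estimated correlation these became adjusted p = 0.35, 0.56 and 0.44. Adjusted over the list alone, 2 renin-angiotensin, 1 sex steroid, 3 androgen response, 1 oxidative stress, 2 erythroid and 1 endothelial genes were lower and 1 skeletal muscle gene was higher. No gene of the TGF-beta signalling list (median -0.05; 6 of 26 at an unadjusted p under 0.05) or the mesothelial list (median 0.10; 2 of 11) passed limma's test, and neither list passed camera (adjusted p = 0.070 and 0.10). Of the 19 lists past camera for surgery, the clock list held with an estimated correlation. Limma's fry passed the clock list (fry adjusted p = 5.7e-06) and the fibroblast, macrophage, matrix protease and lymphocyte lists (fry adjusted p = 0.012 for each).

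Within XY mice, ORC (n = 4) was compared with sham (n = 5). Sult1e1 (-2.66 ± 0.29), Cxcl13 (-2.23 ± 0.34), Pon1 (-1.59 ± 0.22), C7 (-1.36 ± 0.16) and the haptoglobin gene Hp (-1.34 ± 0.25) were lower after ORC. Wee1, a kinase that holds back entry into mitosis, was higher (0.65 ± 0.10), as were Cys1 (0.54 ± 0.10), Col14a1 (0.53 ± 0.08), Mlana (0.36 ± 0.06) and Slc6a7 (0.34 ± 0.06). In all, 30 genes passed limma's test, 6 higher and 24 lower. Of the 16 clock genes limma passed 0 over all genes (9 at an unadjusted p under 0.05), while 6 were higher and 0 lower adjusted over the list alone, among them Per2 (0.69 ± 0.15) and Hlf (0.55 ± 0.11). The clock list had a median of 0.28 (camera adjusted p = 0.0071, but adjusted p = 0.33 with an estimated correlation), and Dbp differed by 0.41 ± 0.19 and Arntl by -0.49 ± 0.24. White adipocyte genes (median -0.45) and sympathetic neuron genes (median -0.98) were lower as groups in this comparison (camera adjusted p = 1.4e-08 and 9.9e-06), which became adjusted p = 0.33 for both with an estimated correlation. The neuron difference rested largely on XY sham 1 and 4, with list means of 9.61 and 9.38. XY sham 2, 3 and 5 stood at 6.76, 7.12 and 6.97, within the XY ORC range of 6.41 to 7.62. The count was 4 when only these 2 groups were fitted, 5 without XY sham mice 1 and 4, 125 with the RNA integrity number as a covariate (45 higher, 80 lower) and 76 with array weights (25 higher, 51 lower). With 1 array left out it ranged from 14 (without XY ORC 3) to 79 (without XX ORC 4).

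Within XX mice, ORC (n = 4) was compared with sham (n = 4). Dbp was 4.20-fold higher after ORC (2.07 ± 0.20), and the clock repressors Nr1d2 (1.51 ± 0.16), Nr1d1 (1.35 ± 0.21), Bhlhe41 (1.16 ± 0.14) and Per3 (1.02 ± 0.10) were higher with it. Arntl (-2.18 ± 0.26) and Npas2 (-2.07 ± 0.26), the activating arm of the clock, were lower, by 4.55-fold and 4.21-fold. Sult1e1 (-2.33 ± 0.31), Avpr1a (-1.54 ± 0.14) and C7 (-1.46 ± 0.17) were also lower. In all, 80 genes passed limma's test, 15 higher and 65 lower. Of the 16 clock genes, 10 were higher and 2 lower (median 0.84, camera adjusted p = 1.5e-07, and adjusted p = 0.042 with an estimated correlation), and adjusted over the list alone 11 were higher and 4 lower. Of 38 elastic fibre and collagen genes 5 were lower, among them Lox (-0.87), Eln (-0.89), Col4a1 (-0.49) and Thbs1 (-0.66), and adjusted over the list alone 25 were (median -0.36, camera adjusted p = 1.5e-17, but adjusted p = 0.31 with an estimated correlation). XX ORC 4 had the lowest mean of this list, 9.07 against 9.33 to 9.37 in the other XX ORC mice. Without it the median was -0.26, and Lox (-0.74), Eln (-0.76), Col4a1 (-0.45) and Thbs1 (-0.62) did not pass limma's test (adjusted p = 0.099, 0.12, 0.089 and 0.11). The count was 508 when only these 2 groups were fitted (373 higher, 135 lower) and 784 without XY sham mice 1 and 4 (522 higher, 262 lower), so more genes were higher than lower in both. It was 30 with the methods' unmoderated two-way fit, 23 with the sympathetic neuron mean as a covariate, 6 with the brown adipocyte mean added (5 higher, 1 lower) and 450 with array weights (114 higher, 336 lower). With 1 array left out it ranged from 26 (without XX sham 2) to 114 (without XX sham 4).

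The tissue markers differed between the same XX groups. The sympathetic neuron list was higher in XX ORC than in XX sham mice (median 1.55, camera adjusted p = 5.5e-09), as were the brown adipocyte (1.10, 1e-05), white adipocyte (0.66, 1.1e-07), oxidative phosphorylation (0.45, 1.5e-11), sterol synthesis (0.26, 0.00029), nerve and Schwann cell (0.25, 0.00044) and interferon response (0.13, 0.022) lists. The smooth muscle contractile list was lower (-0.34, 7e-10, and -0.25 without XX ORC 4), as were the fibroblast (-0.30, 1.6e-09), macrophage (-0.32, 1.3e-09), erythroid (-0.43, 0.0015) and immediate early (-0.13, 0.014) lists. With an estimated correlation the adjusted p of each of these 12 lists lay between 0.30 and 0.65. Adjusted over the list alone, 9 sympathetic neuron, 9 brown adipocyte, 12 white adipocyte and 3 nerve genes were higher and 12 smooth muscle genes were lower, while over all genes limma passed none of these (9, 12, 13, 5 and 18 at an unadjusted p under 0.05). The adrenal cortex list did not pass (0.20, adjusted p = 0.090). In the kidney and liver lists, which were chosen after the values had been seen, limma passed no gene in any comparison, with medians here of 0.06 over 11 genes and 0.58 over 12 genes (none at an unadjusted p under 0.05) and of -0.40 and 0.08 between XY ORC and XY sham mice (4 and 1 at an unadjusted p under 0.05).

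Between XY and XX mice, 9 genes passed for ORC in both, all in the same direction in both, where independent lists would share 0.0749. They were Sult1e1, C7, Avpr1a (-1.03 in XY and -1.54 in XX mice), Dpep1 (-1.13 and -1.34), Lbp, the lipopolysaccharide-binding protein gene (-0.82 and -0.84), Sult5a1 (-0.48 and -0.60), Bmper (-0.42 and -0.36), the predicted gene Gm11816 (-0.61 and -0.50) and Wee1 (0.65 and 0.53). These 9 are the complete overlap, and Gm11816, Sult5a1, Bmper and Lbp were chosen after their values were seen. Both comparisons came from the same fit with a shared spread per gene, so their lists are not independent and 0.0749 may be too low. Of the 30 genes called in XY mice, 28 differed in the same direction in XX mice, and of the 80 called in XX mice, 61 did so in XY mice. Across all genes the changes after ORC in XY and XX mice correlated at r = -0.44 (Spearman's rho -0.01), and genes are not independent replicates.

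**Figure D3:**
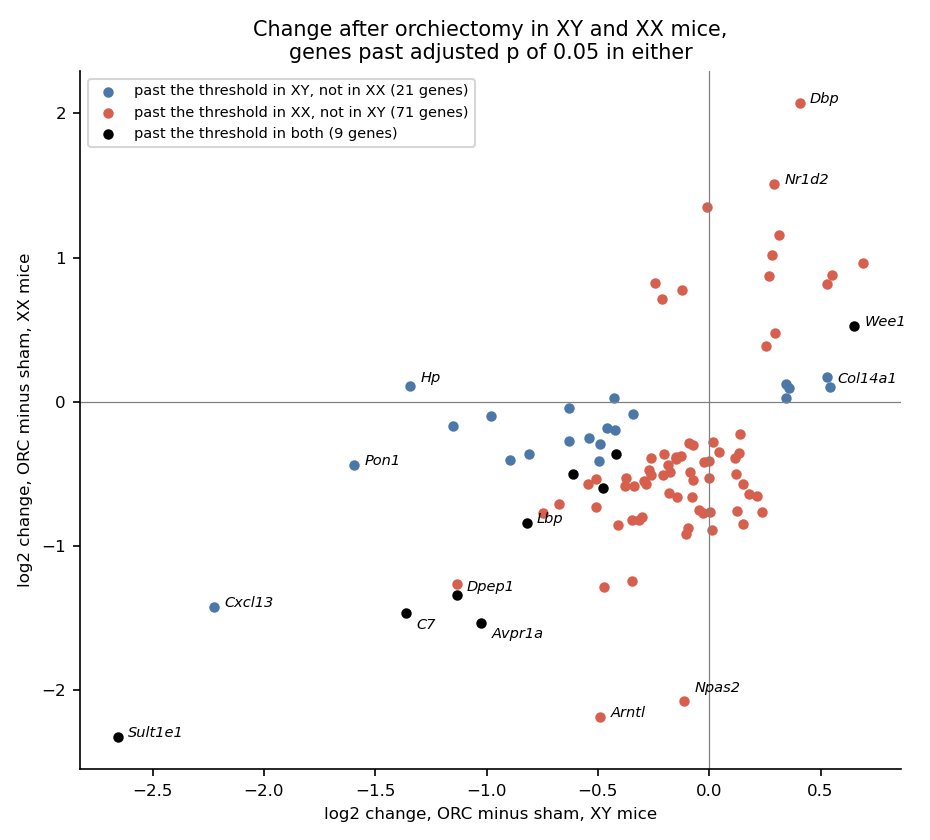
Log2 change after orchiectomy in XY mice (horizontal axis; 4 ORC against 5 sham) and in XX mice (vertical axis; 4 against 4) for each gene past an adjusted p of 0.05 in either. The 9 genes past it in both (black) lie in the lower left or upper right, from Sult1e1 (-2.66 and -2.33) to Wee1 (0.65 and 0.53), while Dbp, Nr1d2, Arntl and Npas2 stand apart along the XX axis.

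Among sham mice, XX (n = 4) was compared with XY (n = 5). Besides Xist (5.69 ± 0.10) and Tsix (0.76 ± 0.09), the clock activators Npas2 (1.96 ± 0.25) and Arntl (1.73 ± 0.24) and the Rho GTPase regulator Arhgap20 (0.99 ± 0.18) were higher in XX mice. Besides Uty (-2.30 ± 0.06), Eif2s3y (-2.22 ± 0.11) and Kdm5d (-1.82 ± 0.08), Dbp (-1.77 ± 0.19) and the fatty acid transporter Slc27a2 (-1.87 ± 0.38) were lower. Dbp stood at 6.98 ± 0.10 (SD) in XX sham against 8.75 ± 0.42 in XY sham, 9.16 ± 0.33 in XY ORC and 9.05 ± 0.21 in XX ORC mice. In all, 92 genes passed limma's test, 57 higher and 35 lower, 76 of them autosomal. Of the 16 clock genes, 3 were higher and 8 lower (median -0.61, camera adjusted p = 2e-07, and adjusted p = 0.021 with an estimated correlation), and adjusted over the list alone 5 were higher and 11 lower. Of the escape genes, 6 of 13 were higher. The fat cell gene Cidec (-1.13), 1 of 21 white adipocyte genes, was lower, and that list had a median of -0.51 (camera adjusted p = 4.1e-11, but adjusted p = 0.30 with an estimated correlation), while the sympathetic neuron list had a median of -1.74 (camera adjusted p = 4.1e-11, but adjusted p = 0.30 with an estimated correlation). There 11 white adipocyte and 12 sympathetic neuron genes were lower adjusted over the list alone. XY sham 1 and 4 (neuron list means 9.61 and 9.38) enlarged the neuron difference. XY sham 2, 3 and 5 (6.76, 7.12 and 6.97) also lay above all XX sham mice (6.05 to 6.71). The count was 488 with the RNA integrity number as a covariate (190 higher, 298 lower), 226 with array weights (161 and 65), 22 without XY sham mice 1 and 4 (12 and 10), 12 with the sympathetic neuron mean as a covariate (5 and 7) and 11 when only these 2 groups were fitted (4 and 7), and with 1 array left out it ranged from 26 (without XX sham 2) to 178 (without XX ORC 4).

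**Figure D4:**
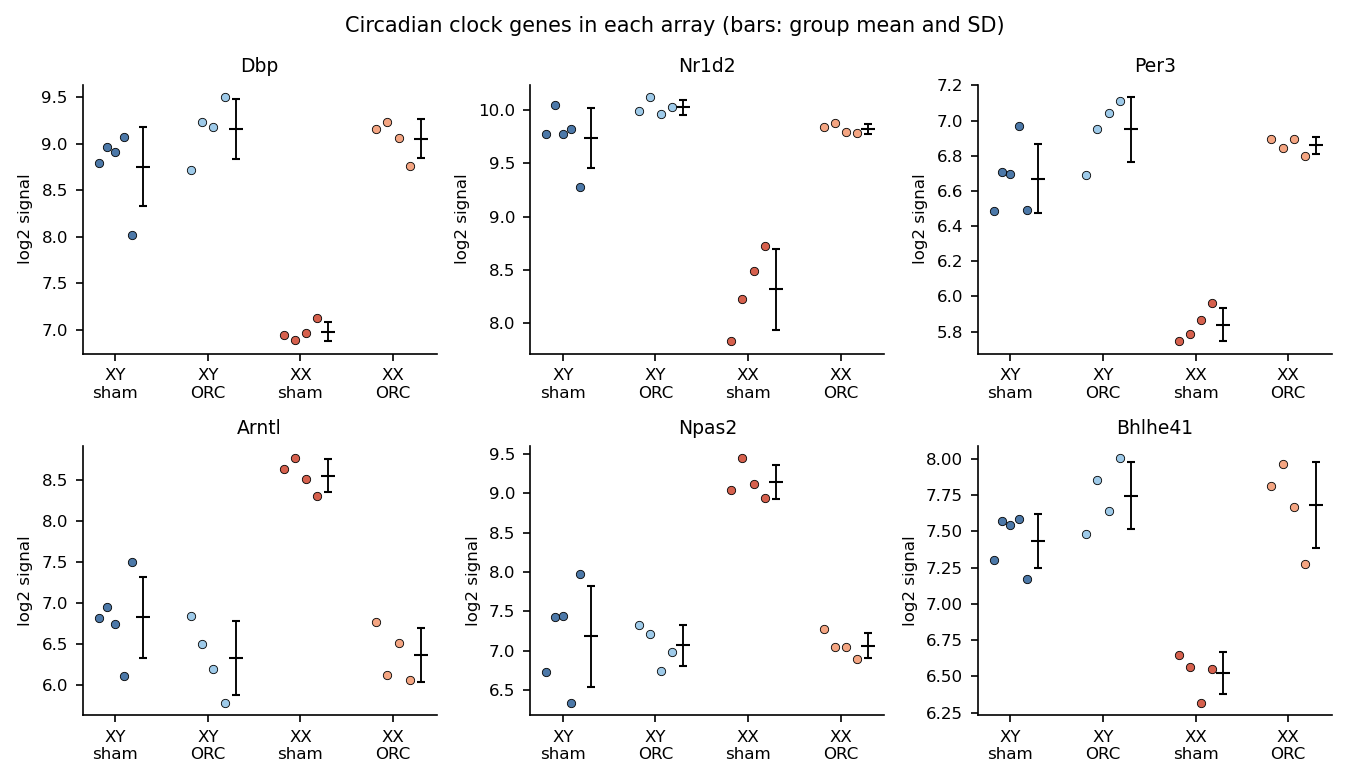
Log2 signal (vertical axis) of 6 circadian clock genes in each mouse (points) by group (horizontal axis), with the group mean and SD as bars. The 4 XX sham mice lie below the other 13 mice for Dbp (6.89 to 7.13) and Per3 (5.75 to 5.96) and above them for Npas2 (8.94 to 9.44) and Arntl (8.30 to 8.76).

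Among ORC mice, XX (n = 4) was compared with XY (n = 4). Xist (5.598 ± 0.10) and Tsix (0.69 ± 0.10) were higher and Uty (-2.15 ± 0.06), Eif2s3y (-2.15 ± 0.12) and Kdm5d (-1.69 ± 0.08) were lower in XX mice, and these were all 5 genes past limma's test. The number of autosomal genes past it was 0 (1674 at an unadjusted p under 0.05). Of the 16 clock genes, limma passed 0 (1 at an unadjusted p under 0.05), and the list had a median of -0.08 (camera adjusted p = 0.14). Of 38 elastic fibre and collagen genes, Col3a1 (-0.79, adjusted p = 0.063) and Col1a1 (-0.71, adjusted p = 0.11) were nearest to the threshold, and adjusted over the list alone 25 were lower (median -0.37, camera adjusted p = 1e-23, but adjusted p = 0.30 with an estimated correlation). The smooth muscle list was lower (median -0.25, camera adjusted p = 1.2e-08) and the sympathetic neuron list higher (1.07, 2.8e-06) in XX ORC than in XY ORC mice, and both became adjusted p = 0.35 with an estimated correlation. XX ORC 4 was lowest on the elastic fibre and collagen list (9.07) and on the smooth muscle list (9.36 against 9.70 to 9.78 in the other XX ORC mice). Without it these medians were -0.31 and -0.16 (camera adjusted p = 3e-15 and 0.00072). The count was 16 with array weights (6 higher, 10 lower), and with 1 array left out it ranged from 4 to 8 (without XY sham 5).

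The interaction asks whether the change after ORC differed between XX and XY mice. Cntn6, a neuronal adhesion gene, went from 5.27 ± 0.10 (SD) in XX sham to 4.62 ± 0.11 in XX ORC mice and from 4.75 ± 0.12 to 4.97 ± 0.05 in XY mice, a difference of changes of -0.86 ± 0.10 (SE; limma adjusted p = 0.0041). Rasl11a, a Ras-like GTPase gene, went from 7.38 ± 0.10 to 6.80 ± 0.11 in XX and from 6.81 ± 0.14 to 6.96 ± 0.04 in XY mice, a difference of -0.72 ± 0.10 (adjusted p = 0.041). These 2 were the genes past the threshold, and 3724 had an unadjusted p under 0.05. The next smallest p-values belonged to Dbp (1.67 ± 0.27, adjusted p = 0.093), Spry1 (-0.36), Bhlhe40 (0.90), Nr1d2 (1.22), Npas2 (-1.96), Per3 (0.74), Cidec (1.56) and Lonrf3 (-0.49), none of which passed. The count was 0 with the sympathetic neuron mean as a covariate and 10 with array weights (3 higher, 7 lower), and with 1 array left out it ranged from 1 to 10 (without XX sham 4).

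At the level of lists, 16 passed camera for the interaction and none held with an estimated correlation. The sympathetic neuron genes differed in their response by a median of 2.57 between XX and XY mice (camera adjusted p = 1.4e-13), the elastic fibre and collagen genes by -0.44 (7.4e-14), the smooth muscle genes by -0.51 (1.1e-09), the oxidative phosphorylation genes by 0.61 (2e-15) and the clock genes by 0.31 (0.00057). Without XX ORC 4 the elastic fibre and collagen and the smooth muscle lists had medians of -0.36 and -0.40 (camera adjusted p = 1.4e-08 and 1e-05). With an estimated correlation each of these 5 had an adjusted p = 0.31. Adjusted over the list alone, 13 sympathetic neuron and 7 clock genes were higher and 30 elastic fibre and collagen, 18 smooth muscle and 4 clock genes were lower, while limma passed none of them over all genes (13 sympathetic neuron, 12 clock, 30 elastic fibre and collagen, 20 smooth muscle and 15 oxidative phosphorylation genes at an unadjusted p under 0.05). The neuron value of 2.57 was enlarged by XY sham 1 and 4 (list means 9.61 and 9.38), though all 16 lists also passed camera without them.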

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

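The tests of the size of the clock changes, of the time of day, of the neuron genes of XY sham mice, of the neuron and fat genes of XX ORC mice, of the shared genes within XY mice and of the splits for autosomal genes in sham mice, and the kidney and liver lists, were chosen only after the results were seen.

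The clock genes of XX sham mice stood apart from the other 3 groups, with 12 of 16 past the threshold for ORC minus sham in XX mice. RNA quality and a single deviating array are argued against, since 11 members passed with the RNA integrity number as a covariate and at least 10 with any XX array left out. With nerve and fat tissue as covariates 5 of 16 passed, under the 6 set beforehand for that explanation, but nerve and fat tissue as the source of the size of the changes is argued against, since a median share of 1.09 (0.76 to 1.29) of the log2 changes of the 12 was left, each more than 2 SE from 0, with Dbp going from 2.07 ± 0.20 to 2.24 ± 0.26 and the median SE from 0.156 to 0.222. The calls of Npas2 (-2.07 ± 0.26 to -1.58 ± 0.26) and Bhlhe40 (0.78 ± 0.11 to 0.59 ± 0.11) ended as their changes shrank, and the other 5 lost calls ended with larger errors. All 15 genes assigned to an arm of the clock differed in XX sham mice in the direction of that arm, so a different time of day at collection cannot be told apart from a biological difference of XX mice with testes, which was not tested, because no collection times are given and the group is the same.

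Neuron signal differed within XY sham mice, and neuron and fat signal differed between XX sham and XX ORC mice. Sympathetic ganglion tissue or adrenal medulla in XY sham 1 and 4 cannot be told apart as a source, since those arrays were picked by the same signal that 14 of 14 further neuron genes show, and since Pnmt, with a range of 0.29 there, stayed at 6.37 or below on every array while XY sham 4 also had an adrenal cortex list mean of 6.98. For XX ORC mice a stray ganglion in a single array is argued against, since 4 of 4 arrays lay above the highest XX sham array. A lower share of smooth muscle against all other cell types is argued against by the endothelial, fibroblast, macrophage and erythroid lists, 4 of 4 with a median below 0. The endothelial median was only -0.05 (camera adjusted p = 0.45). Other lists went the other way, the T and B lymphocyte list with a median of 0.35 (camera adjusted p = 6e-05), the adrenal cortex list with 0.20 and the mesothelial list with 0.09. The values therefore speak only against a rise shared by all other cell types. A larger share of perivascular nerve and fat, from dissection or from the mice themselves, stays open and was not tested.

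For ORC in both XY and XX mice 9 genes passed, 8 lower and Wee1 higher. Without XY sham 1 and 4, 9 of 9 passed for surgery, which decides nothing on kidney and ganglion tissue in 2 XY sham arrays, because that comparison keeps all XX arrays, where the same genes passed. Kidney and ganglion tissue in 2 XY sham arrays as the source of the changes in XY mice is argued against, since within XY mice a median share of 1.01 (0.94 to 1.09) of the log2 changes was left, each more than 2 SE from 0, while 4 of 9 still passed and the other 5 calls ended with fewer arrays and larger errors (Wee1 from 0.65 ± 0.10 to 0.68 ± 0.12). With both list means as covariates 9 of 9 passed for surgery. This decides little, since that comparison averages XY and XX mice, where the neuron list went opposite ways. As an explanation, nerve and fat tissue in the aorta samples is argued against by values compared after the results were seen. Neuron and brown adipocyte medians were -0.98 (resting largely on XY sham 1 and 4) and -0.12 in XY, but 1.55 and 1.10 in XX mice. Each of the 9 genes changed in the same direction in both. Kidney tissue in XY sham 3 and 5 (Kap 7.29 and 7.84) stays open for the changes in XY mice and was not tested. It does not bear on those in XX mice, where Kap did not exceed 4.86 and the kidney list had a median of 0.06 for ORC minus sham. An effect of the loss of the testes also stays open and was not tested.

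For other splits of the arrays, chance is argued against for ORC minus sham in XX mice (80 genes, highest other 2, with 1 of 35 splits as large, the real one included). That is the smallest share that 35 splits can give. The share was also under the 0.05 set beforehand for surgery (189, highest other 650, 2 of 100) and ORC minus sham in XY mice (30, highest other 1070, 2 of 100). In both, another split gave several times as many genes as the real one, so chance is not excluded there. The splits for the interaction (2, highest other 1912, 2 of 100) decide nothing, since they exchanged arrays among all groups and so also broke both main effects. Those for the autosomal genes of genotype (21, highest other 2, 1 of 100) and of XX minus XY in sham mice (76, highest other 1376, 2 of 100) decide nothing either. P-values were adjusted over all genes there, so sex-linked calls, which the complement fixes, eased the threshold of the real split alone. For all genes of genotype (32, highest other 2, 1 of 100), of XX minus XY in sham mice (92, highest other 1424, 2 of 100) and of XX minus XY in ORC mice (5, highest other 0, 1 of 35) the splits say nothing about chance, since 10, 16 and 5 of the genes are annotated to the X or Y chromosome and put the real split ahead by themselves. Sry, annotated to the Y chromosome but carried by the transgene here, is counted among them where it passed. In the highest splits for surgery, the interaction, sham mice and XY mice XY sham 1 and 4 lay on one side apart from XY sham 2 and 3, which points to a structure of the samples, and the split for surgery also exchanged all XX sham and XX ORC arrays. The real splits for ORC in XX mice and for the interaction had the largest gap in the sympathetic neuron mean of all their splits (1.73 and 2.64). The splits for ORC in XX mice therefore do not part that result from this tissue signal.

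XX ORC 4 also stood apart in the second principal component (-39.74, with -9.68 to 18.06 in all other arrays), the SD over genes (1.58), the median positive control (8.22) and the percent of genes at or above a signal of 4.2 (98.85).

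Some arrays lay far from the rest of their group, with the gap as a share of the group's range given for each. Chance marks about 1 in 20 groups, and 8 of 216 gene groups (3.7%) and 7 of 136 list groups (5.1%) were marked. C7 was 10.25 in XX ORC 4 against 11.14 to 11.31 in the others (0.837), and Serpina3n was 7.14 there against 7.83 to 7.97 (0.832). Ccl8 was 6.26 in XY ORC 1 against 5.37 to 5.48 (0.878), and Cys1 was 7.06 there against 7.45 to 7.52 (0.849). In XX ORC 2, Cys1 was 7.10 against 7.01 to 7.02 (0.883). Dbp was 8.02 in XY sham 5 against 8.79 to 9.08 (0.728), Eif2s3x 9.65 in XY sham 2 against 9.51 to 9.54 (0.742), and Xist 4.35 in XY ORC 4 against 4.19 to 4.22 (0.866). The distal X list was 6.29 in XX ORC 4 against 6.58 to 6.64 (0.84), and the elastic fibre and collagen list 9.07 there against 9.33 to 9.37 (0.89). The macrophage list was 7.41 in XX sham 3 against 7.57 to 7.59 (0.862), and the cell cycle list 5.48 in XX ORC 3 against 5.25 to 5.28 (0.886). The adrenal cortex list was 6.98 in XY sham 4 against 5.77 to 5.92 (0.87), the liver list 8.21 there against 4.96 to 5.75 (0.755), and the oxidative phosphorylation list 9.70 in XY sham 5 against 8.73 to 9.01 (0.714).

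The response to ORC differed between XX and XY mice for Cntn6 (-0.865) and Rasl11a (-0.725). It differed past camera's threshold, as medians, for the sympathetic neuron (2.567), brown adipocyte (1.198), white adipocyte (0.949), oxidative phosphorylation (0.605), sterol synthesis (0.576), nerve and Schwann cell (0.446), adrenal cortex (0.366), interferon response (0.364), circadian clock (0.308) and X-linked neighbour (0.171) lists. It was negative for the smooth muscle (-0.514), elastic fibre and collagen (-0.436), TGF-beta (-0.275), matrix protease (-0.261), immediate early (-0.26) and skeletal muscle (-0.186) lists. With an estimated correlation these 16 lists had an adjusted p of 0.31 to 0.50, and camera kept 0 of them.

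Among 16788 probe sets with no single gene symbol, limma passed 5 for genotype, 6 for surgery, 8 for XX minus XY in sham mice, 1 in ORC mice, 1 for ORC minus sham in XY mice and 5 in XX mice. The largest absolute log2 differences were 4.59, 1.29, 4.62, 4.57, 1.4 and 1.3.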

How the results depend on the processing

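The omission of XY sham 1 and 4 and the list means as covariates were tests chosen only after the results were seen. Counts of genes past the threshold moved with the processing, and the cause was not tested except where fewer arrays were fitted. With array weights they were 80 for genotype (32 as reported), 67 autosomal (21), 303 for surgery (189), 10 for the interaction (2), 226 for XX minus XY in sham mice (92), 16 in ORC mice (5), 76 for ORC minus sham in XY mice (30) and 450 in XX mice (80). With the methods' unmoderated two-way fit they were 20, 10 autosomal, 89 for surgery, 1 for the interaction and 30 for ORC in XX mice. With the RNA integrity number as a covariate they were 51, 39 autosomal, 9 for the interaction, 488 in sham mice, 125 in XY and 51 in XX mice. With a replicate block they were 89, 75 autosomal, 324, 11 for the interaction, 19 in ORC mice, 60 in XY and 657 in XX mice. The labels give no animal shared by arrays of 1 replicate number, and not every same-number pair was over 0.1. The 24 such pairs had r from -0.427 to 0.599 (median 0.18, 15 over 0.1; other numbers -0.066) and 5 of 17 arrays correlated best with their own number, a hint from the data and not the design. Without XY sham 1 and 4 they were 20, 10 autosomal, 513 for surgery, 4 for the interaction, 22 in sham mice, 5 in XY and 784 in XX mice. With the neuron list mean as a covariate they were 13 autosomal, 330 for surgery, 0 for the interaction, 12 in sham mice, 17 in XY and 23 in XX mice, and with both list means 0 for the interaction, 12 in sham mice and 6 in XX mice. With only the groups compared they were 11 in sham mice, 4 in XY and 508 in XX mice. Without a filter they were 1 for the interaction and 50 in XX mice, with a stricter filter 0 for the interaction, with centred arrays 1 for the interaction and 13 autosomal (surgery split into 32 higher and 155 lower, against 52 and 137), and with quantile normalization repeated 0 for the interaction and 8 in ORC mice. The balance of directions turned in some settings. Surgery had 324 higher and 189 lower without XY sham 1 and 4 (52 and 137 as reported). ORC in XX mice had 522 and 262 without them, 373 and 135 with only the groups compared, and 5 and 1 with both list means (15 and 65). XX minus XY in sham mice had 190 and 298 with the RNA integrity number, 65 and 70 with a block, 5 and 7 with the neuron mean, 4 and 8 with both means and 4 and 7 with only the groups compared (57 and 35). Genotype had 11 and 9 without XY sham 1 and 4 and with the unmoderated fit, 26 and 25 with the RNA integrity number and 17 and 16 with quantile normalization repeated (14 and 18).

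With an estimated correlation camera passed 2 lists for genotype (12 as reported), 1 for surgery (19), 0 for the interaction (16), 2 in sham mice (18), 1 in ORC mice (21), 0 in XY (25) and 1 in XX mice (20), and fry passed 4, 5, 3, 5, 4, 1 and 5. With the neuron list mean as a covariate 10 lists passed in sham mice. The sympathetic neuron list turned from a median of -0.36 for genotype to 0.18 (adjusted p = 0.0119) without XY sham 1 and 4, arrays with the highest values of that list. Of 133 named calls, 86 to 133 were kept across settings (119 of 120 with the stricter filter, 41 of 62 with only the groups compared) and 0 reversed. Low signal limits Sult1e1, Uty and Xist, whose lower values stood near the negative controls.

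With 1 array left out the counts ranged from 16 to 58 for genotype, 6 to 46 autosomal, 79 to 216 for surgery, 1 to 10 for the interaction, 26 to 178 in sham mice, 4 to 8 in ORC mice, 14 to 79 in XY and 26 to 114 in XX mice. List counts ranged from 10 to 14, 17 to 22, 15 to 19, 17 to 21, 17 to 22, 20 to 25 and 18 to 21. Genotype was 20 without XY sham 1, 58 without 5, 18 without XY ORC 3, 16, 20, 21 and 16 without XX sham 1, 2, 3 and 4, and 19 without XX ORC 3. Its autosomal count was 10, 12, 13 and 46 without XY sham 1, 2, 3 and 5, 12 and 8 without XY ORC 2 and 3, 6, 10, 11 and 6 without XX sham 1 to 4, and 13, 13, 9 and 13 without XX ORC 1 to 4. Surgery was 114 and 107 without XY sham 2 and 3, 81, 92 and 95 without XY ORC 2, 3 and 4, 92, 79 and 114 without XX sham 1, 2 and 4, and 105 without XX ORC 4. The interaction was 1 without XY sham 3, any XY ORC array, XX sham 1, 2 or 3, or XX ORC 1, 5 without XY sham 5 and 10 without XX sham 4. In sham mice it was 38, 173 and 56 without XY sham 1, 3 and 4, 29, 26, 32 and 171 without XX sham 1 to 4, and 61 and 178 without XX ORC 3 and 4, and in ORC mice 8 without XY sham 5. ORC in XY mice gave 19 and 47 without XY sham 4 and 5, 47, 19 and 14 without XY ORC 1, 2 and 3, and 79 without XX ORC 4. ORC in XX mice gave 53, 48 and 47 without XY ORC 2, 3 and 4, 27, 26 and 36 without XX sham 1, 2 and 3, and 32, 42 and 32 without XX ORC 2, 3 and 4.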

Other observations

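The test of the distal X segment was chosen only after the results were seen. It asked whether a second active copy of the segment from Tmsb4x to Hccs on the Y chromosome of XY mice could be present, which would lower these genes in XX against XY mice. The 8 measured genes had a median of -0.05, 3 of them were positive, and 6 of 8 had a lower 95% bound above -0.4, which argues against such a copy. Tlr8 differed by -0.25 and Tlr7 by -0.15, while Arhgap6 differed by 0.11, and none of these passed for genotype.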
